A study of Homo sapiens with 48 samples.

How the data were processed

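Gene expression was measured in HK-2 human renal proximal tubular epithelial cells exposed to CsA, Fk, Ra, Nnm or vehicle. Per the labels' protocols, cells were seeded 24 h before treatment and treated near confluence, total RNA was extracted with a silica column kit, and biotin-labelled cRNA was hybridised to 1 array per sample. The deposited table holds log2 expression values of 48 arrays and 54675 probe sets, which were made with GCRMA per the submitters' processing notes, with its version not given. Values ran from 0.7212 to 16.11, no 2 arrays held the same values, and correlations between arrays of a group ran from 0.9417 to 0.9952. The number of arrays, 3 per group, limits the precision, since arrays give no counts. The compounds' full names, their doses and the vehicle amounts are not given in the sources used here, so the short names of the labels were kept.

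The deposited values were used without further normalization. After 62 control probe sets were set aside, 41091 probe sets had 1 gene symbol in the platform annotation, 1801 had several and 11721 were not listed there. Probe sets with several symbols were not used, and those not listed were tested apart. Of the 41091, 41043 had a gene number found in the reference table, and the update changed 0 symbols. Probe sets had to exceed log2 4 in at least 3 arrays, which left 20960, and each gene was represented by its probe set of highest mean over all arrays, giving 11356 genes, of which 5660 had more than 1 probe set. With each probe set tested on its own, 50 genes had probe sets called in opposite directions in some comparison, and 0 of these 56 cases concern a gene named by the rule there. For 13 named genes another probe set had the other sign without both being called: CLU, ABCB1, HSPA5, KLHL24, SC5D, TRPM7, CYCS, NDUFS1, NRG1, ABCC5, RFC5, ERO1A and ATP6V0E1.

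A linear model with 1 mean per group over all 48 arrays and 16 groups was fitted with limma 3.58.1 (lmFit and eBayes, statmod 1.5.0, R 4.3.3), and 23 contrasts were tested two-sided: 10 treatments against the controls of their set and time, high against low dose of Nnm, Fk against Ra, the treatment effect at the later against the earlier time, and the effect of CsA against those of Fk and Ra. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each contrast. All groups entered a single fit so that they shared an estimate of the spread. Camera of limma tested, per treatment comparison, whether the genes of a list moved relative to other genes, with a correlation preset to 0.01, adjusted over 270 tests of 27 lists in 10 comparisons, and again with an estimated correlation.

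The design, the gene lists, the rule for named genes and the first alternatives were fixed before the data were examined. The 29 lists were ER chaperones and ER-associated degradation, ATF4 and CHOP targets, NRF2 targets, p53 targets, G2 and mitosis, DNA replication, cholesterol synthesis and uptake, fatty acid and glycerolipid synthesis, fatty acid oxidation, hypoxia and glycolysis, ribosome biogenesis and MYC targets, the mitochondrial respiratory chain, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, heat shock, metallothioneins and zinc response, extracellular matrix and TGF-beta response, lysosome and autophagy, kidney injury markers, proximal tubule transport and brush border, drug transporters and xenobiotic metabolism, calcineurin, immunophilin and mTOR pathways, ion and water homeostasis, immediate early genes, apoptosis and cell death, and markers of fibroblasts, of endothelium, of leukocytes and of other nephron segments. Lists of leukocytes (0 of 12 measured) and of the loop, distal tubule, collecting duct and podocyte (2 of 12) were not tested.

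Named genes were, per treatment comparison, the 6 largest rises and 6 largest falls among called genes whose 3 treated and 3 control values did not overlap, and up to 4 called members of each list with the largest change. For dose, time and compound comparisons they were the 4 largest in each direction, without the overlap condition for differences of effects. HAVCR1, LCN2, CLU, GDF15, HMOX1, CDKN1A, DDIT3, HSPA5 and ABCB1 were always taken. The text gives those that passed with any array left out first, and counts the others.

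Groups share replicate numbers in the labels, and whether these pair the arrays was checked from the correlation of deviations from the group means. In the CsA set all 18 pairs of same-numbered arrays correlated above 0.1 (0.24 to 0.93, mean 0.54, against -0.23 between other numbers), and in the Nnm set all 45 (0.14 to 0.79, mean 0.45, against -0.21), so values with the replicate number as a block are given beside results of these sets where they differ. In the Fk and Ra set not every pair passed 0.1, so its arrays were not taken as paired.

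Correlations of effects were computed across genes for 45 pairs of treatment comparisons. For pairs with shared controls, 100 simulations of unchanged groups gave correlations from 0.478 to 0.525. The overlap of calls was set against that of independent lists. For each count, other splits of the same arrays were drawn, 10 for 2 groups of 3 and 100 for differences of effects, together with all that part the pairs of the CsA and Nnm sets (32, or 80 where CsA is set against Fk or Ra).

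Alternatives were no filter or a filter at log2 6, each probe set tested on its own, arrays centred on their median, quantile normalization, a trended and robust variance, a further 2-fold threshold, fits of the compared groups or sets alone, the replicate block, and each array left out in turn. Added after the data were seen were fits without Ra 48 h replicate 2 and Fk 12 h replicate 3, without the Nnm or CsA arrays of one number, and single-set fits with the block. Giving centred values for Ra at 48 h was decided after the median of all genes was seen to lie at -0.178 there (0.074 with centred arrays and 0.012 with quantile normalization).

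The steps were tested on simulated data in which known changes were added to 50 genes for each size. For CsA at 48 h, 18%, 58%, 88% and 90% of genes were recovered at log2 changes of 0.5, 1, 1.5 and 2, with 8 false calls among 11356 genes. For the effect of Ra with time 2%, 26%, 66% and 70% were recovered, with 0 false calls. A shift of 0.5 added to the ATF4 and CHOP list was called with 0 of 26 other lists. Genes were drawn independently there, while the correlation estimated within that list in the data was 0.499. The simulation therefore does not test the preset correlation of the list tests.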

Results

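Gene expression was measured on 48 oligonucleotide arrays in HK-2 cells, an immortalised line of human renal proximal tubular epithelial cells. The cells were exposed to vehicle or to 1 of 4 compounds, which the labels name CsA, Fk, Ra and Nnm and place together in a group called Tox 1. The arrays formed 3 sets, each with vehicle controls of its own: CsA at 12 h and 48 h, Fk and Ra at 12 h and 48 h with shared controls, and Nnm at a low and a high dose at 24 h and 48 h with shared controls. Each of the 16 groups held 3 arrays, called biological replicates in the labels. Doses other than the words low and high are not given in the sources used here. The number of arrays limited the precision: the median SE of a log2 difference over the 11356 genes tested was 0.26 within a set, and 0.36 for a difference between differences. Levels below are log2 values with the SD over n = 3 arrays, changes are log2 differences from the controls of the same set and time with their SE, and adjusted p-values are from limma. Where a group mean lay under log2 4, the level of the low filter, the size of a difference from it is uncertain, and this is said of each called gene named. Shifts of gene lists were tested with a preset correlation between genes. With an estimated correlation 0 of the 69 called shifts passed (lowest adjusted p = 0.184), so each rests on that preset value. Another split of the arrays, applied to all comparisons, gave 67 list calls. The upper quartile of the probe set values was 6.203 in Ra 48 h replicate 2 and 6.846 in Fk 12 h replicate 3, against up to 7.243 elsewhere.

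**Figure D1:**
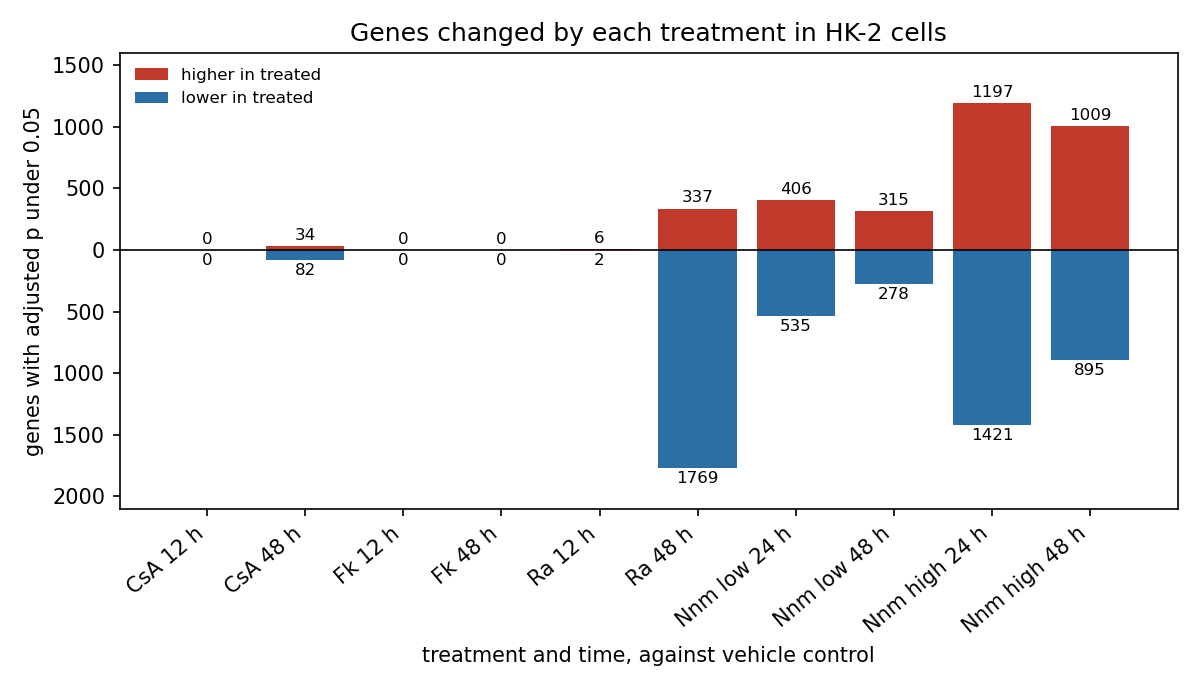
Bars give the number of genes, of 11356 tested, that were higher (above 0) or lower (below 0) than the vehicle controls of the same set and time in each treatment comparison of 3 against 3 arrays. The high dose of Nnm at 24 h changed 2618 genes, while CsA at 12 h and Fk at both times changed 0.

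In cells given CsA for 12 h, the chaperones of the endoplasmic reticulum and its protein degradation machinery shifted upward as a list: the median change of the 24 measured members was 0.44 (camera adjusted p = 2.62e-21, or adjusted p = 0.433 with an estimated correlation). HSPA5, the main chaperone of that compartment, stood at 13.98 ± 0.33 against 12.98 ± 0.17 in the controls, a difference of 0.99 ± 0.32 that missed the test across genes (adjusted p = 1). The 28 genes of G2 and mitosis shifted downward by a median of -0.19 (adjusted p = 6.57e-05, or adjusted p = 0.986 with an estimated correlation). Smaller upward shifts were found for 30 targets of the stress transcription factors ATF4 and CHOP (0.19; adjusted p = 0.00533, or adjusted p = 0.986 with an estimated correlation). Others were those of 19 genes of cholesterol synthesis and uptake (0.17; adjusted p = 0.00576, or adjusted p = 0.899 with an estimated correlation) and 17 genes of fatty acid and glycerolipid synthesis (0.21; adjusted p = 0.00159, or adjusted p = 0.824 with an estimated correlation). The 25 genes of ribosome biogenesis shifted by -0.08 (adjusted p = 0.0274, or adjusted p = 0.986 with an estimated correlation). No single gene passed the test over all genes. Limma found 0 genes, with 36 at an unadjusted p under 0.05 where 568 were expected by chance. The lowest adjusted p was 0.162. With the replicate number as a block 1 gene was called, and 1 was called without control replicate 2. The shift of the ATF4 and CHOP targets missed the threshold without replicate 2 of every group (adjusted p = 0.0651), that of fatty acid synthesis without replicate 1 (0.0907) and that of ribosome biogenesis without replicate 3 (0.75). With no filter on low values the ATF4 and CHOP, cholesterol and fatty acid shifts were not called (0.613, 0.474 and 0.335), and with centred arrays the ribosome shift was not (0.056).

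After 48 h of CsA, genes of DNA replication fell. Of the 29 measured, 19 were lower past the test over all genes and 27 when adjusted over the list alone, with a median change of -1.25 (camera adjusted p = 6.74e-38, or adjusted p = 0.184 with an estimated correlation). ASF1B, a histone chaperone of replicating chromatin, fell from 8.29 ± 0.41 to 5.69 ± 1.33 (-2.6 ± 0.38, adjusted p = 0.000684). Also lower were the helicases BRIP1 (-2.74) and BLM (-2.11), the replication initiation factor MCM10 (-2.35) and the ribonucleotide reductase subunit RRM2 (-1.85), with MCM10 and BLM under log2 4 in treated cells (3.34 and 3.54). None of the 28 genes of G2 and mitosis passed the test over all genes, 11 were lower when adjusted over the list alone, and their median was -0.77 (adjusted p = 6.97e-13, or adjusted p = 0.668 with an estimated correlation). The chaperone and degradation genes of the endoplasmic reticulum again lay higher, by a median of 0.66 (adjusted p = 8.02e-09, or adjusted p = 0.769 with an estimated correlation), with 1 of 24 rising over all genes and 5 over the list alone. SEC61B, a subunit of the protein translocation channel, rose by 0.72 ± 0.17. PPIB, or cyclophilin B, rose from 12.75 ± 0.57 to 13.77 ± 0.19. The strongest rises were those of NEBL (1.97 ± 0.51), TMEM140 (1.92 ± 0.44) and LINGO2 (1.9 ± 0.34), while the death ligand gene TNFSF10 (-1.5) and the interferon-induced OAS3 (-1) fell. LINGO2 lay under log2 4 in the controls (3.36). Cholesterol genes shifted by -0.41 with none called singly (adjusted p = 0.00461, or adjusted p = 0.862 with an estimated correlation).

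In all, 116 genes changed after 48 h of CsA, 34 higher and 82 lower (58 and 77 with centred arrays), and the values of the 3 treated and 3 control arrays did not overlap for 1618 genes, against 1136, or 10%, by chance. With the replicate number as a block 498 genes changed (165 higher, 333 lower). Without the other sets in the fit there were 2 calls, 13 with the block, and with the 2 groups alone 0. Under that block CDKN1A, the p21 cell cycle inhibitor, rose by 1 (adjusted p = 0.0305, against 0.334 without it) and ABCB1, the P-glycoprotein gene, fell by 0.82 (adjusted p = 0.0305, against 0.419). The unblocked count varied with the array left out: there were 2 without CsA replicate 2 and 5 without control replicate 1. There were 49 (34 of them among the 116) without CsA replicate 3 and 66 (53) without control replicate 3. Without control replicate 2 there were 192, and without CsA replicate 1 391. Each of these fits breaks a pair and keeps the partner, so they do not single out an array. With the block and all arrays of a number left out, there were 274 without number 1 and 74 without number 3. Without number 2 that count stayed within 1.5 times of 116. Of the 20 genes named by the fixed rule, ASF1B alone passed whichever array was left out, and 19 failed without CsA replicate 2. The list of inflammatory cytokines also shifted (-0.61 over 20 genes, 1 lower over the list alone; adjusted p = 0.032, or adjusted p = 0.986 with an estimated correlation), but not without replicate 2 (0.399). The kidney injury markers shifted by -0.19 over 24 genes (adjusted p = 0.048, or adjusted p = 0.668 with an estimated correlation), but not without replicate 2 (0.228), without replicate 3 (0.133) or with centred arrays (0.0601).

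With Fk gene lists were called under the preset correlation, and no single gene passed the test over all genes. At 12 h the ATF4 and CHOP targets lay higher by a median of 0.51 (camera adjusted p = 5.52e-06, or adjusted p = 0.862 with an estimated correlation). The 23 interferon-stimulated genes lay higher by 0.34, with 1 rising over the list alone (adjusted p = 0.000489, or adjusted p = 0.668 with an estimated correlation). Ribosome biogenesis genes lay lower by -0.23 (adjusted p = 4.43e-06, or adjusted p = 0.668 with an estimated correlation). At 48 h the 19 genes of cholesterol synthesis and uptake shifted downward by -0.47, with 1 lower over the list alone (adjusted p = 1.41e-11, or adjusted p = 0.433 with an estimated correlation). The 28 genes of hypoxia and glycolysis shifted upward by 0.24, with 1 higher over the list alone (adjusted p = 8.89e-08, or adjusted p = 0.587 with an estimated correlation). So did 27 genes of the extracellular matrix and the TGF-beta response, by 0.28 (adjusted p = 0.00351, or adjusted p = 0.668 with an estimated correlation). DNA replication genes shifted by -0.22 (adjusted p = 0.00079, or adjusted p = 0.986 with an estimated correlation), though not with no filter on low values (0.076). The 9 metallothionein and zinc genes shifted by 0.35 (adjusted p = 0.0149, or adjusted p = 0.986 with an estimated correlation), but not without replicate 2 (0.504).

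Further Fk shifts at 12 h depended on single replicate numbers. The 21 immediate early genes had a median of -0.32 (adjusted p = 0.00345, or adjusted p = 0.862 with an estimated correlation), which turned upward without replicate 3 (0.776). The inflammatory cytokines had a median of -0.25 (adjusted p = 0.048, or adjusted p = 0.986 with an estimated correlation; 0.162 without replicate 2 and 0.212 without replicate 3). The 19 genes of ion and water homeostasis had one of -0.21 (adjusted p = 0.0308, or adjusted p = 0.862 with an estimated correlation; 0.0715 and 0.565). The 25 genes of the mitochondrial respiratory chain shifted by -0.09 (adjusted p = 0.0214, or adjusted p = 0.986 with an estimated correlation), but not without replicate 1 (0.238) or replicate 2 (0.224). Of single genes limma called 0 at 12 h, with 712 at an unadjusted p under 0.05, and 0 at 48 h, with 311. With the replicate number as a block it called 1 at 12 h and 8 at 48 h, and with no filter on low values 9 and 12. Leaving out 1 array gave up to 5 genes at 12 h: 4 without Fk replicate 1, 5 without Fk replicate 2, 1 without Fk replicate 3 and 1 without control replicate 2. At 48 h it gave 2 without control replicate 1, 5 without control replicate 3 and 1 without Fk replicate 1.

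Ra at 12 h raised KLHL24, a gene of a ubiquitin ligase adaptor, from 7.31 ± 0.17 to 9.39 ± 0.37 (2.08 ± 0.32, adjusted p = 0.00186), the sole named call kept whichever array was left out. The other 5 genes that rose were the interferon-induced IFIT2 (2.12), CREBRF (2.09), UBALD2 (1.99), NATD1 (1.92) and the sulfotransferase SULT1C2 (1.67), and the 2 that fell were the ribosome assembly factor LTV1 (-0.89) and the decoy receptor TNFRSF10C (-0.82). Interferon-stimulated genes shifted upward as a list by a median of 0.47, with 1 of 23 called over all genes and 7 over the list alone (camera adjusted p = 2.67e-10, or adjusted p = 0.264 with an estimated correlation). Ribosome biogenesis genes shifted downward as a list by -0.41, with 0 of 25 called over all genes and 7 over the list alone (adjusted p = 6.97e-13, or adjusted p = 0.433 with an estimated correlation). Heat shock genes shifted by -0.22 over 16 genes (adjusted p = 0.000364, or adjusted p = 0.843 with an estimated correlation). Those of the respiratory chain shifted by -0.15 (adjusted p = 0.000647, or adjusted p = 0.862 with an estimated correlation). Upward shifts of 21 targets of the antioxidant factor NRF2 (0.24; adjusted p = 0.0286, or adjusted p = 0.986 with an estimated correlation), matrix genes (0.24; adjusted p = 0.0267, or adjusted p = 0.848 with an estimated correlation) and 26 lysosome and autophagy genes (0.2, with 1 higher over the list alone; adjusted p = 0.0187, or adjusted p = 0.986 with an estimated correlation) were called too. They were not called without replicate 1 (0.0724 and 0.086 for the NRF2 and matrix lists) or replicate 3 (0.051 and 0.0765 for the NRF2 and lysosome lists). In all, 8 genes changed, 6 higher and 2 lower (11 and 8 with quantile normalization), with 879 at an unadjusted p under 0.05. The values of the 3 treated and 3 control arrays did not overlap for 3651 genes, against 1136 by chance, and 651 genes were called with these 2 groups alone in the fit. Leaving out control replicate 2 gave 2 calls, control replicate 3 gave 1, Ra replicate 1 gave 1 and Ra replicate 2 gave 3, of which 2 were among the 8.

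After 48 h of Ra, targets of ATF4 and CHOP fell and cell cycle genes rose. The median of all genes lay at -0.178 here, so this paragraph gives changes with arrays centred on their median. Of the 30 ATF4 and CHOP targets 22 fell, with a median of -1.82. INHBE, an inhibin subunit gene, fell by 6.38 (SE 0.93 from all groups; adjusted p = 5.08e-05), with widely spread Ra values. The mitochondrial folate enzyme ALDH1L2 changed by -3.7, the cystathionine lyase CTH by -3.65, the cystine transporter SLC7A11 by -3.46 and DDIT3, which encodes CHOP itself, by -3.24. Of 24 chaperone and degradation genes of the endoplasmic reticulum 10 fell (median -0.95), among them DNAJC3 (-2.4), HERPUD1 (-2.23) and HSPA5 (-1.35), and the stress sensor gene ERN1 fell by 3.42. Other falls were those of ANK2, an ankyrin (-3.73 ± 0.44; adjusted p = 4.4e-06), SESN2 (-2.56), the growth factor VEGFA (-1.56), the cholesterol enzyme HSD17B7 (-1.19) and the calcineurin regulator RCAN1 (-1.16). Of 29 DNA replication genes 24 rose and 1 fell (median 1.13), with CCNE2 at 2.11 and CCNE1 at 1.87, and of 28 genes of G2 and mitosis 19 rose (median 1.05). LYPD1 rose by 2.6 ± 0.4, ASF1B by 2.24, the ubiquitin ligase subunit SKP2 by 2.23, TNFSF10 by 1.83 and the death receptor FAS by 1.23.

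The deposited values gave 2106 changed genes for Ra at 48 h, 337 higher and 1769 lower, or 16% higher. Centred arrays gave 1028 higher and 903 lower, and quantile normalization 843 higher and 1038 lower. Without Ra replicate 2, the array of low upper quartile, 817 changed (423 higher, 394 lower), without control replicate 1 878 and without control replicate 2 1042. Of the 78 genes named by the fixed rule 27 passed whichever array was left out, among them every gene given in the paragraph on centred values. On the deposited values the list tests gave adjusted p = 1.77e-13 for the ATF4 and CHOP targets (25 of 30 fell, 28 over the list alone; median -2.07, or adjusted p = 0.618 with an estimated correlation). They gave 2.54e-17 for DNA replication (16 rose and 1 fell, 23 and 1 over the list alone; 0.88, or adjusted p = 0.492 with an estimated correlation). The values were 5.96e-07 for the endoplasmic reticulum genes (17 fell, 21 over the list alone; -1.2, or adjusted p = 0.848 with an estimated correlation) and 1.4e-13 for G2 and mitosis (9 rose, 15 over the list alone; 0.8, or adjusted p = 0.668 with an estimated correlation). With the set alone 984 genes were called. Without Ra replicate 2 the median of the ATF4 and CHOP targets was -1.69, with 15 falling. Other lists had fewer calls without it too. Of the endoplasmic reticulum genes 4 of 24 fell (median -0.92, and -1.47, -2.03 and -0.06 in replicates 1 to 3 against the controls of their number). Of DNA replication genes 13 of 29 rose (0.99) and of G2 and mitosis genes 7 of 28 (1). The matrix list (median 0.5, with 0 rising and 3 falling, 0 and 2 over the list alone; adjusted p = 0.00107, or adjusted p = 0.668 with an estimated correlation) shifted upward, while its 3 falling members LOX, SNAI2 and COL1A1 did not pass without Ra replicate 2 (0.276, 0.105 and 0.371). The immediate early list shifted by 0.14 (2 rose, 1 over the list alone; adjusted p = 0.00438, or adjusted p = 0.862 with an estimated correlation). Both shifts were not called with no filter on low values (0.0999 and 0.111). Cholesterol genes shifted by -0.62 (6 fell, 7 over the list alone; adjusted p = 0.0417, or adjusted p = 0.986 with an estimated correlation) and metallothioneins by 0.73 (0 called; adjusted p = 0.0031, or adjusted p = 0.862 with an estimated correlation). Kidney injury markers had a median of 0 and a mean of 0.05 (1 rose, 0 over the list alone; adjusted p = 0.0479, or adjusted p = 0.668 with an estimated correlation). Without replicate 2 these 3 were not called (0.14, 0.176 and 0.242), nor were cholesterol genes without replicate 3 (0.201), and the injury markers without replicate 1 (0.0956) and with centred arrays (0.0675).

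**Figure D2:**
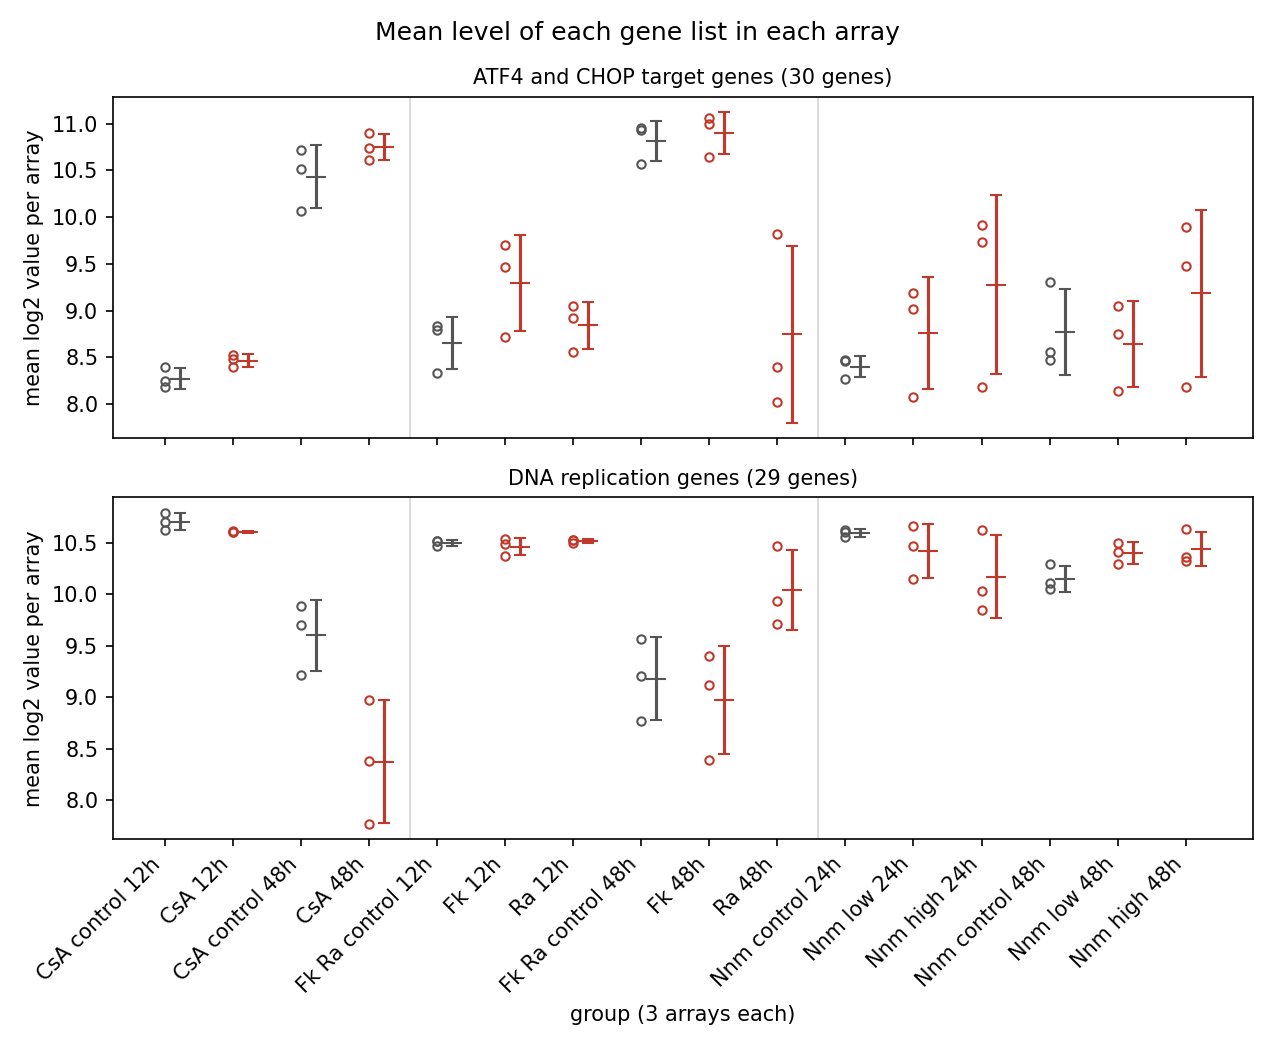
Points are the mean log2 value per array of 30 ATF4 and CHOP target genes and of 29 DNA replication genes, by group, with bars for the mean and SD of 3 arrays; controls are grey and treated arrays red. Ra at 48 h lay below its controls for the first list and above them for the second.

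After 24 h of Nnm, SLC16A14, a member of the monocarboxylate transporter family, rose from 2.66 ± 0.32 to 8.38 ± 1.19 at the low dose (5.71 ± 0.84, adjusted p = 8.4e-05) and to 9.52 ± 1.89 at the high dose (6.85 ± 0.84, adjusted p = 5.33e-06). PCLO rose by 4.16 and 4.27 and the histone demethylase KDM7A by 3.65 and 3.77 at the low and high dose, and the pseudogene ZBED10P fell (-2.55 and -3.08). The antioxidant enzymes TXNRD1 (1.64 ± 0.34) and NQO1 (1.34 ± 0.25) rose at the low dose, SLC7A11 (3.27 ± 0.75) and OSGIN1 (2.49 ± 0.52) at the high dose, as parts of the NRF2 list. Control levels of SLC16A14, KDM7A (3.6) and OSGIN1 (3.24) lay under log2 4. That list shifted by 0.74 at the low dose (4 rose, 9 rose and 1 fell over the list alone; camera adjusted p = 1.92e-05, or adjusted p = 0.637 with an estimated correlation). The shift was 0.88 at the high dose (11 rose, 14 rose and 1 fell over the list alone; adjusted p = 2.74e-05, or adjusted p = 0.637 with an estimated correlation). Genes of the respiratory chain fell: 9 of 25 at the low dose (12 over the list alone; median -0.36; adjusted p = 8.26e-07, or adjusted p = 0.668 with an estimated correlation). The high dose lowered 12 (13 over the list alone; -0.4; adjusted p = 5.89e-06, or adjusted p = 0.766 with an estimated correlation). At the high dose SDHA of complex II changed by -1.19 ± 0.21, NDUFS1 of complex I by -1 and CYC1 of complex III by -0.95. Ribosome biogenesis fell with 9 of 25 at the low dose (20 over the list alone; -0.65; adjusted p = 6.51e-11, or adjusted p = 0.492 with an estimated correlation). Of these 17 fell and 1 rose at the high dose (20 and 1 over the list alone; -0.64; adjusted p = 6.61e-08, or adjusted p = 0.637 with an estimated correlation). BYSL changed by -1.22 and -1.55. Cholesterol genes fell with 2 of 19 at the low dose (3 over the list alone; -0.43; adjusted p = 0.00452, or adjusted p = 0.862 with an estimated correlation). The high dose lowered 8 and raised 1 (10 and 1 over the list alone; -0.71; adjusted p = 0.00116, or adjusted p = 0.848 with an estimated correlation). ACAT2, an early enzyme of that pathway, changed by -1.69 ± 0.38 at the high dose.

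Other lists shifted at 24 h of Nnm. Lysosome and autophagy genes lay higher, by 0.36 at the low dose (2 rose; adjusted p = 0.00943, or adjusted p = 0.986 with an estimated correlation; 0.105 without replicate 1). The shift was 0.45 at the high dose (7 rose, 9 over the list alone; adjusted p = 0.000442, or adjusted p = 0.862 with an estimated correlation). There the autophagy genes GABARAPL1 and UVRAG rose by 1.38 and 1.17. Interferon-stimulated genes shifted by 0.5 at the low dose (2 rose, also over the list alone; adjusted p = 0.00461, or adjusted p = 0.825 with an estimated correlation). Their shift was 0.54 at the high dose (5 rose and 2 fell, also over the list alone; adjusted p = 0.0415, or adjusted p = 0.955 with an estimated correlation). The latter was not called with the replicate number as a block (0.0507), without replicate 2 (0.082) or without replicate 3 (0.0503). The high dose also shifted the ATF4 and CHOP list by 0.58 (4 rose, 1 over the list alone; adjusted p = 0.00516, or adjusted p = 0.986 with an estimated correlation) and DNA replication by -0.43 (9 fell, 9 against 1 that rose over the list alone; adjusted p = 0.0214, or adjusted p = 0.986 with an estimated correlation; 0.105 without replicate 1). At the high dose the mTOR complex gene RICTOR rose by 0.89 and the lipogenic factor SREBF1 and the acyltransferase AGPAT2 fell (-1.07 and -0.95). At the low dose 941 genes changed, 406 higher and 535 lower, and with the block 2049. Of the 3 treated and 3 control values, 4314 genes had no overlap, against 1136, or 10%, by chance. Fewer were called without control replicate 1 (433), control replicate 3 (194), treated replicate 1 (217) or treated replicate 3 (259), and 9 of the 40 named genes passed whichever array was left out. At the high dose 2618 changed, 1197 higher and 1421 lower, with 1508 to 1680 without control replicate 3 or 1, 853 without treated replicate 1 and 1119 without treated replicate 3. There 25 of 79 named genes passed whichever array was left out.

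After 48 h of Nnm, TXNIP, a thioredoxin inhibitor that limits glucose uptake, rose from 5.89 ± 1.55 to 12.08 ± 0.4 at the low dose (6.19 ± 0.76, adjusted p = 5.4e-06) and 12.27 ± 0.53 at the high dose (6.38 ± 0.76, adjusted p = 1.62e-06). SLC16A14 rose by 6.16 and 6.43 from a control level under log2 4 (2.46). The long noncoding RNA UCA1 (-3.39 and -3.66) and the keratin KRT20 (-3.7 and -3.51) fell at the low and high dose, UCA1 to levels under log2 4 (3.8 and 3.53). In the controls TXNIP stood at 9.32 ± 0.36 at 24 h, above its 48 h level (difference -3.42, adjusted p = 0.185). Of glycolysis and its control, PDK1, a kinase that holds pyruvate back from mitochondria, fell (-1.45 and -1.66), as did the triose isomerase TPI1 (-0.65 and -0.7). Respiratory chain genes fell, 10 of 25 at the low dose (16 over the list alone; median -0.43; camera adjusted p = 1.7e-13, or adjusted p = 0.433 with an estimated correlation). With the high dose 12 fell (19 over the list alone; -0.53; adjusted p = 1.19e-12, or adjusted p = 0.489 with an estimated correlation). SDHA changed by -1.2 ± 0.21, CYC1 by -1.09 and ATP5MC1 by -1.21 at the high dose. Interferon-stimulated genes rose, 4 of 23 at the low dose (8 over the list alone; 0.55; adjusted p = 3.73e-05, or adjusted p = 0.618 with an estimated correlation). With the high dose 8 rose (10 over the list alone; 0.64; adjusted p = 0.000114, or adjusted p = 0.637 with an estimated correlation). At that dose OASL rose by 2.28 ± 0.46 and OAS1 by 1.61. Cholesterol genes fell, 2 of 19 at the low dose (4 over the list alone; -0.55; adjusted p = 2.74e-05, or adjusted p = 0.668 with an estimated correlation). With the high dose 6 fell (10 over the list alone; -0.69; adjusted p = 9.54e-06, or adjusted p = 0.668 with an estimated correlation). Ribosome biogenesis genes fell too, 4 of 25 at the low dose (6 over the list alone; -0.45; adjusted p = 5.26e-06, or adjusted p = 0.668 with an estimated correlation). With the high dose 5 fell (8 fell and 1 rose over the list alone; -0.43; adjusted p = 0.000168, or adjusted p = 0.848 with an estimated correlation). TXNRD1 and NQO1 rose by 1.59 and 1.37 at the high dose, where the NRF2 list shifted by 0.62 (5 rose, also over the list alone; adjusted p = 0.0101, or adjusted p = 0.862 with an estimated correlation).

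Further lists shifted at 48 h of Nnm. The low dose shifted G2 and mitosis by 0.47 (0 called; adjusted p = 0.000742, or adjusted p = 0.986 with an estimated correlation). It shifted fatty acid and glycerolipid synthesis by -0.38 (1 fell, 3 over the list alone; adjusted p = 0.00558, or adjusted p = 0.848 with an estimated correlation) and hypoxia and glycolysis by -0.14 (5 fell, 6 over the list alone; adjusted p = 0.0325, or adjusted p = 0.986 with an estimated correlation; 0.0507 without replicate 1 and 0.144 without replicate 2). Fatty acid oxidation, with 18 genes, shifted by -0.18 at the low dose (1 fell, also over the list alone; adjusted p = 0.048, or adjusted p = 0.862 with an estimated correlation), though not with the block (0.0529), without replicate 1 (0.103) or without replicate 3 (0.062). At the high dose it shifted by -0.43 (5 fell, 7 over the list alone; adjusted p = 0.0237, or adjusted p = 0.848 with an estimated correlation; 0.0649 without replicate 1). The dehydrogenase ACADS changed by -1.16 ± 0.22. Immediate early genes shifted by 0.86 at the high dose (4 rose, 5 over the list alone; adjusted p = 0.0274, or adjusted p = 0.986 with an estimated correlation; 0.0816 without replicate 3). The lysosomal protease CTSL rose by 1.38 and the glutathione transferase GSTP1 fell by 0.85 at the high dose. At the low dose 593 genes changed, 315 higher and 278 lower, and with the block 1478. Leaving out a control array gave 276, 373 and 239 for replicates 1 to 3, leaving out a treated array 131, 955 and 230, and 12 of 39 named genes passed throughout. At the high dose 1904 changed, 1009 higher and 895 lower, and with the block 3107. There leaving out a control array gave 1115, 1265 and 1022, leaving out a treated array 578, 2928 and 736, and 27 of 75 named genes passed throughout.

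Between the doses of Nnm few genes were called with all arrays. At 24 h the zinc finger pseudogene ZNF137P was higher at the high dose (4.48 ± 1.08 against 2.68 ± 0.1; adjusted p = 0.0258), and at 48 h CNIH3 (1.91 ± 0.33; adjusted p = 0.02) and the adhesion gene CEACAM1 (1.26 ± 0.24; adjusted p = 0.0384). Their low-dose levels all lay under log2 4 (2.68, 3.09 and 3.45). The 1 and 2 calls compare with 808 and 398 genes at an unadjusted p under 0.05, and with the block there were 5 calls at 48 h. Without high-dose replicate 2 there were 1049 calls at 24 h and 228 at 48 h. At 24 h there were 0 without high-dose replicate 1 or 3 or low-dose replicate 1, and at 48 h 0 without high-dose replicate 1 or 3. ZNF137P, CNIH3 and CEACAM1 each lost their call with 5 of 6 arrays left out (up to 0.603, 0.483 and 1). The single call without low-dose replicate 2 or 3 at 24 h, and without each low-dose array at 48 h, was another gene. Changes from control were smaller in replicate 2. Its slopes across genes on the mean of the others were 0.37, 0.41, 0.22 and 0.28, against 1.09 to 1.39 in replicates 1 and 3. Its dose differences correlated with the others at -0.01 and 0.06, those of replicates 1 and 3 at 0.65 to 0.71. The difference between 3′ and 5′ ACTB control probe sets, which rises as RNA degrades, ran from 1.084 to 1.202 in the treated replicate 2 arrays and from 0.761 to 0.943 in the other treated arrays.

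**Figure D3:**
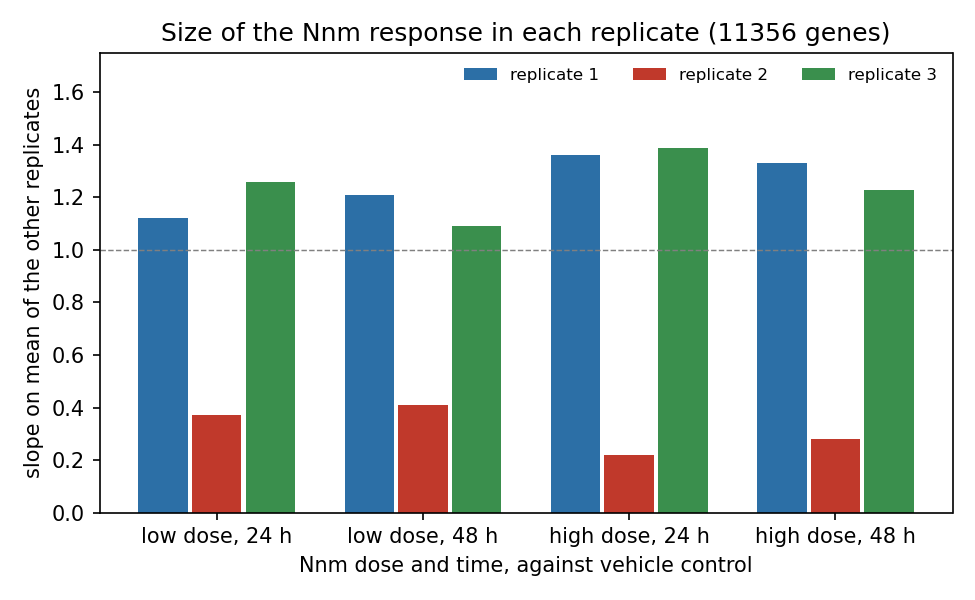
Bars are slopes, across genes, of the log2 changes of each Nnm replicate on the mean change of the other replicates. They are given for 2 doses and 2 times, with a dashed line at 1. The 4 slopes of replicate 2 ran from 0.22 to 0.41 and the other 8 from 1.09 to 1.39.

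Fk and Ra, run side by side, differed at 48 h. INHBE stood at 11.55 ± 0.47 with Fk and 5.2 ± 3.84 with Ra (6.35 ± 0.98, adjusted p = 8.77e-05), and ANK2 (4.43), ALDH1L2 (4.14) and the kinase ITPKA (4.07) were also higher with Fk. The helicase BLM (-2.18), SLFN13 (-2) and cyclin CCNE2 (-1.97) were lower with Fk. These 7 passed whichever array was left out, and TM4SF4 (-2.4, with 3.57 under log2 4 in Fk) did not without Fk replicate 1. In all, 1962 genes differed, 1721 higher and 241 lower with Fk, against 713 and 855 with centred arrays and 835 and 690 with quantile normalization. The median of all genes was 0.198. Against the controls of its number the median change was -0.57 in Ra replicate 2 and 0 in replicates 1 and 3. There were 800 with the set alone in the fit, 555 (296 higher, 259 lower) without Ra replicate 2, 603 without Fk replicate 1, 1162 without Fk replicate 2 and 3062 without Ra replicate 1. At 12 h KLHL24 alone differed (-1.94 ± 0.32; adjusted p = 0.00668), lower with Fk, of 875 genes at an unadjusted p under 0.05. That count was 0 without Fk replicate 3, Ra replicate 1 or Ra replicate 2, 3 without Ra replicate 3, 6 without Fk replicate 1 and 32 without Fk replicate 2. With the replicate number as a block it was 5.

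Set against each other through their own controls, CsA and Ra differed at 48 h. The effect on INHBE was higher with CsA by 7.33 ± 1.38 (adjusted p = 0.000689), and those on IL20RB, ALDH1L2 and CLIP4 by 5.31, 5.29 and 5.21. The effects on ASF1B (-4.59 ± 0.54; adjusted p = 5.03e-06), the pyruvate dehydrogenase kinase PDK4 (-4.3), BRIP1 (-4.21) and BRI3BP (-4.02) were lower with CsA. All 8 passed whichever array was left out, and IL20RB and CLIP4 lay under log2 4 with Ra (3.43 and 2.76). In all, 1873 genes differed, 1343 higher and 530 lower with CsA (935 and 940 with centred arrays, 946 and 939 with quantile normalization), with 1083 without CsA replicate 2, 1153 without its control replicate 1 and 898 without control replicate 1 of the Fk and Ra set. With the replicate number as a block limma called 3011 between CsA and Ra and 20 between CsA and Fk at 48 h, and 2 between CsA and Ra at 12 h. The compounds were run in different sets, and the labels place the CsA arrays at lab 3 and name no lab for the others, so a difference between sets or laboratories in how cells responded is included. At 12 h limma called 0 genes between CsA and Ra (217 at an unadjusted p under 0.05) and 0 between CsA and Fk (165). At 48 h it called 0 between CsA and Fk (696), with 34 without CsA replicate 1, 4 without CsA replicate 3, 10 without its control replicate 2, 14 without Fk replicate 1 and 19 without control replicate 3 of the Fk and Ra set.

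The effect of Ra changed between 12 h and 48 h. Its effect on INHBE was lower at 48 h (-7.51 ± 1.38, adjusted p = 0.00347), and those on ALDH1L2 (-5.5), ANK2 (-5.47) and SLC7A11 (-4.89) were lower too, while those on TM4SF4 (2.76), MAP3K6 (2.19), SKP2 (2.12) and TM4SF18 (1.91) were higher. INHBE, ALDH1L2 and ANK2 passed whichever array was left out, and MAP3K6 lay under log2 4 in the 48 h controls (3.47). In all, 411 effects differed with time, 35 higher and 376 lower at 48 h (148 and 196 with centred arrays, 115 and 188 with quantile normalization). With the set alone in the fit there were 23. Leaving out Ra 12 h replicates 1, 2 and 3 gave 83, 190 and 259, 12 h control replicates 2 and 3 gave 91 and 205, 48 h control replicates 1 to 3 gave 88, 86 and 977, and Ra 48 h replicates 1 and 2 gave 1479 and 87. For the high dose of Nnm the effect on SCGB3A1 alone was higher at 48 h than at 24 h (1.49 ± 0.26; adjusted p = 0.0153). Its means lay under log2 4 in all groups but the high dose at 48 h (3.62, 3.96 and 3.58). The call was lost without 24 h control replicate 2, 48 h control replicate 1 or 3, high-dose replicate 1 or 3 at 24 h or high-dose replicate 3 at 48 h, each with 0 genes, while 216 and 25 genes were called without high-dose replicate 2 at 24 h and at 48 h. Limma called 0 genes for the low dose of Nnm (219 at an unadjusted p under 0.05), 0 for Fk (337; 1 without Fk 12 h replicate 2) and 0 for CsA (327). For CsA, leaving out CsA 48 h replicate 1 gave 10, and 1 gene was called without CsA 12 h replicate 1 or 2, 12 h control replicate 2 or 48 h control replicate 2 or 3.

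Across genes, which are not independent replicates, the effects of the 4 compounds at 48 h were compared as Pearson correlations among 45 pairs of comparisons. CsA and Ra ran opposite (r = -0.44), and 41 genes were lower with CsA and higher with Ra against 2.4 for independent lists, with 6 the other way against 5.3. ASF1B, MCM10, UHRF1 and CCNE2 were among those named in both comparisons. The correlation was 0.14 between CsA and Fk, 0.03 between CsA and the high dose of Nnm, 0.3 between Fk and Nnm and 0.08 between Ra and Nnm. It was 0.32 between Fk and Ra, where unchanged groups against the same controls gave 0.5 by simulation. There the covariance was 0.052 against a simulated 0.055. With the 3 controls split 1 and 2 between Fk and Ra the correlation was 0.081. The doses of Nnm gave r = 0.87 at 24 h (covariance 0.331) and 0.89 at 48 h (0.302), against the same simulated values, with 331 genes higher at both doses at 24 h where independent lists would share 42.8, and 474 lower where they would share 66.9. At 48 h 281 were higher (28) and 256 lower (21.9). Part of the excess of the doses may come from their shared controls, which were not split for these pairs. No gene changed in 1 direction with all 4 compounds at 48 h, which the 0 calls of Fk left no room for. With CsA, Ra and the high dose of Nnm 0 rose and 0 fell, against 0.0896 and 1.01 for independent lists. At an unadjusted p under 0.05 in each comparison there were 2, chosen here after their values were seen: OGA, which removes sugar marks from proteins, was higher in each (0.73, 0.59, 0.96 and 1.23 for CsA, Fk, Ra and Nnm) and ACAT2 was lower (-1.21, -0.81, -0.88 and -1.49). Fk and Ra share their controls, so these 2 are not set against a chance count.

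Genes often read as markers of tubular injury or toxic stress changed in few comparisons. The injury marker HAVCR1, also known as KIM-1, passed in none of the 10 treatment comparisons and ran from -0.94 ± 0.37 (high dose of Nnm, 48 h; adjusted p = 0.0788) to 0.13 ± 0.37 (Ra, 12 h). With the replicate number as a block the former passed (adjusted p = 0.014). LCN2, or NGAL, ran from -1.18 ± 1.7 to 0.81 ± 1.7. In the CsA set it stood at 10.8 to 13.3 in all arrays of replicate 3 and 3.6 to 8.1 in the others. CLU, or clusterin, was higher by 0.76, 0.6, 0.62 and 0.57 in the Nnm comparisons (low dose at 24 h and 48 h, then high dose), which passed with the block (adjusted p = 0.00268, 0.0178, 0.00622 and 0.0139) and not without it (0.0971, 0.236, 0.12 and 0.182). GDF15 was higher by 1.16 ± 0.7 with the high dose of Nnm at 24 h, which passed with the block alone (adjusted p = 0.0422, against 0.241). HMOX1, the inducible heme oxygenase, rose in that comparison alone, from 8.05 ± 0.2 to 10.78 ± 2.73 (adjusted p = 0.00578), a call lost with either of 2 treated arrays left out (up to 0.107, without replicate 3). DDIT3 rose there too, by 2.18 ± 0.79 (adjusted p = 0.0408), a call lost with any of 5 arrays left out (up to 0.264, without treated replicate 1).

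Of the lists fixed before the data were examined, 7 shifted in none of the 10 treatment comparisons. Their camera adjusted p-values ran from 0.198 to 0.946 for 21 genes of apoptosis and cell death, from 0.437 to 0.977 for 27 genes of the calcineurin, immunophilin and mTOR pathways, from 0.11 to 0.977 for 18 drug transporters and xenobiotic enzymes, from 0.122 to 0.977 for 22 p53 targets and from 0.247 to 0.929 for 14 genes of proximal tubule transport and the brush border. In the last of these the glucose transporter SLC2A2 rose by 2.71 ± 0.65 from a level under log2 4 (2.7) with the low dose of Nnm at 48 h and the brush border peptidase DPP4 by 1.18 and 1 with the low and high dose at 48 h, calls of DPP4 that were lost without low-dose replicate 1 (0.0542) and control replicate 3 (0.053). Of markers of other cell types, 3 of 10 endothelial genes were measured (0.051 to 0.892; PECAM1 rose by 0.82 with the high dose of Nnm at 48 h). So were 3 of 10 fibroblast genes (0.111 to 0.94; COL1A1 fell by 1.04 with Ra at 48 h on the deposited values, a call lost with any of 3 arrays left out, up to 0.371 without Ra replicate 2). Measured were also 2 of 12 genes of the loop, distal tubule, collecting duct and podocyte, and 0 of 12 leukocyte genes, so that the latter lists were not tested. Of the 270 pairs of list and treatment comparison 69 were called.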

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

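The counts over other splits and the tests of RNA quality, array scale, normalization and mislabelling were chosen only after the results were seen. Groups held 3 arrays, too few for a test of single outlying arrays.

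Treatment effects that differed between times or compounds stand out here. For Ra, 411 effects differed between 12 h and 48 h, and 2 of 100 splits drawn gave as many, the highest other 567. The count was unsteady: 23 with the set alone in the fit and 83 to 1479 with 1 array left out. The splits also hold the treatment effect, since exchanging treated and control arrays at 1 of the times adds the 2 effects (937 genes), so they do not test this difference against chance. Among the 411 genes the effects on TM4SF4 (2.76), MAP3K6 (2.19), SKP2 (2.12) and TM4SF18 (1.91) were higher at 48 h, and those on INHBE (-7.51), ALDH1L2 (-5.5), ANK2 (-5.47) and SLC7A11 (-4.89) lower, while INHBE rose by 7.2 in controls. For the high dose of Nnm, 1 gene differed between 48 h and 24 h, SCGB3A1 (1.49, with 3 of its 4 group means under log2 4), and 35 of 100 splits gave at least as many, the highest 3046. Of the 32 splits that part all pairs of arrays 12 did, the highest 4248, from the split that exchanges treated and control arrays at 1 of the times. The treatment effect thus enters these splits too, and they say nothing on chance. Between CsA and Ra, 1873 genes differed at 48 h, and 1 of 100 splits gave as many, the real one, with 1293 as the highest other, as did 1 of the 80 that part all CsA pairs. Other splits break up both effects, so they do not test their difference against chance. The effects of CsA exceeded those of Ra on INHBE (7.33), IL20RB (5.31), ALDH1L2 (5.29) and CLIP4 (5.21) and lay below them on ASF1B (-4.59), PDK4 (-4.3), BRIP1 (-4.21) and BRI3BP (-4.02).

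Where a difference of effects had 0 calls, each of 100 splits had to give as many, so the splits test nothing there. The highest other split gave 1044 for CsA by time, 22 for Fk by time, 735 for the low dose of Nnm by time, 9 and 998 for CsA against Fk at 12 h and 48 h, and 247 for CsA against Ra at 12 h. Among the splits that part all pairs of the CsA and Nnm sets the highest were 2 for CsA by time, 2539 for the low dose of Nnm by time (treated and control exchanged at 1 time), 1 and 998 for CsA against Fk, and 2 for CsA against Ra. The 1044 of CsA by time thus came from splits that keep arrays of a number together, and the 998 points to a structure of the samples other than the CsA numbers.

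Probe sets that the annotation does not list, 2165 past the filter, also changed against the controls: 17 with CsA at 48 h, 6 with Fk at 48 h, 146 with Ra at 48 h, 98 and 55 with the low dose of Nnm at 24 h and 48 h, and 288 and 239 with the high dose.

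With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and where the real count was 0 each of them gives as many. The real and the highest other count were 0 and 66 for CsA 12 h (10 splits as large), 116 and 412 for CsA 48 h (2), 0 and 3 for Fk 12 h (10), 0 and 228 for Fk 48 h (10), 8 and 0 for Ra 12 h (1), 2106 and 1363 for Ra 48 h (1) and 1962 and 1519 for Fk against Ra at 48 h (1). They were 941 and 1 for the low dose of Nnm at 24 h (1), 593 and 4 at 48 h (1), 2618 and 530 for the high dose at 24 h (1), 1904 and 24 at 48 h (1), 1 and 3 for Fk against Ra at 12 h (3), and 1 and 1209 (4) and 2 and 654 (6) for the doses of Nnm at 24 h and 48 h. Of gene lists 69 were called, against 67 in the highest other split applied to all comparisons (1), and of genes called in the same direction with all 4 compounds at 48 h 0 against 0 (10). Where the numbers pair the arrays, the splits that part all pairs, as the real one does, gave at most 0 for CsA 12 h and 48 h, 0 for the low dose of Nnm at both times, 447 and 0 for the high dose, and 0 and 4 between the doses. Higher counts such as 412 for CsA 48 h and 1209 for the doses at 24 h came from splits that kept 2 arrays of a number together, which points to the replicate numbers as a structure of these arrays.

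The response to Nnm was weaker in replicate 2, with slopes of 0.22 to 0.41 on the others. Its dose difference correlated with that of the others at -0.01 at 24 h. An exchange of high and low dose predicts a clearly negative value and right labels a positive one, so this does not decide. An exchange alone would not give low slopes at the low dose too, where they were 0.37 and 0.41. Quantile normalization on top of the deposited values left the highest slope at 0.42. The Nnm groups already had similar mean upper quartiles (7.14 to 7.2), so this step could change little. It does not test the submitters' own normalization. RNA quality stays open: the treated replicate 2 arrays lay above all other treated arrays in the ACTB 3′ to 5′ difference by at least 0.14, but so did the controls of replicate 2 (1.06 to 1.15 against 0.716 to 0.819), so that RNA quality and a weaker exposure or response of that replicate cannot be told apart. A biological difference between replicates was not tested.

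Ra at 48 h gave mostly lower genes and a deep fall of ATF4 and CHOP targets. The unequal split may come from the scale of Ra replicate 2, because 51.8% of called genes were higher without it, against 16% with it. That scale does not account for the ATF4 and CHOP fall, with a median of -1.69 without the array. Changes of replicate 2 correlated with those of the others at 0.6 across genes. This does not decide on a wrong label, as a 12 h array could give a positive value too. Replicate 3, its label untested, had ATF4 and CHOP (8.401) and replication (10.471) means within its 12 h control ranges. The effect of Ra ran against the time change of the CsA set controls (-0.61 across genes). The change in this pathway under Ra, with list medians of -1.14, -2.94 and -1.57 in replicates 1 to 3, remains a biological hypothesis found and tested on the same arrays.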

How the results depend on the processing

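Tests without the arrays or replicate numbers in doubt (Ra 48 h replicate 2, Fk 12 h replicate 3 and the Nnm and CsA arrays of one number), fits of a single set with the block, and every setting tried on the change of the controls with time were chosen only after the results were seen. In the following, Nnm dose stands for the high against the low dose and by time for an effect at the later against the earlier time. Values are counts of called genes unless named otherwise, given where a count moved by more than 1.5 times, and the cause was not tested except where fewer arrays or genes entered the fit.

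With no filter on low values the counts were 2 for CsA 12 h, 9 for Fk 12 h, 12 for Fk 48 h, 13 for Ra 12 h, 7 for Nnm dose 24 h, 18 for Nnm dose 48 h and 9 for Fk vs Ra 12 h. The same setting gave 2 for CsA by time, 2 for Fk by time, 6 for low Nnm by time, 3 for CsA vs Fk at 12 h, 3 for CsA vs Ra at 12 h and 0.272 for the correlation of Fk and Ra at 48 h. A stricter filter, at log2 6, left 0 for Nnm dose 24 h, 0 for Nnm dose 48 h and 0 for high Nnm by time. Testing each probe set on its own gave 14 for Ra 12 h, 3413 for Ra 48 h, 1426 for low Nnm 24 h, 968 for low Nnm 48 h, 4371 for high Nnm 24 h, 3252 for high Nnm 48 h and 1 for Nnm dose 48 h. It also gave 3304 for Fk vs Ra 48 h, 3 for CsA by time, 5 for high Nnm by time, 3 for CsA vs Fk at 48 h, 3099 for CsA vs Ra at 48 h and 0.064 for the correlation of CsA and Nnm at 48 h, with more features tested. Quantile normalization gave 19 for Ra 12 h, 1 for Nnm dose 48 h, 2 for Fk vs Ra 12 h, 2 for high Nnm by time and 4 for CsA vs Fk at 48 h. Arrays centred on their median gave 20 for Ra 12 h, 1 for Nnm dose 48 h and 0 for high Nnm by time. A trended and robust variance gave 1 for Nnm dose 48 h. A further requirement of a 2-fold change left 76 for CsA 48 h, 895 for Ra 48 h, 436 for low Nnm 24 h, 305 for low Nnm 48 h, 1172 for high Nnm 24 h and 926 for high Nnm 48 h. With the compared sets alone in the fit there were 2 for CsA 48 h, 1 for Fk 48 h, 984 for Ra 48 h and 0 for Nnm dose 24 h. Likewise there were 0 for Nnm dose 48 h, 800 for Fk vs Ra 48 h, 23 for Ra by time and 0 for high Nnm by time. With the 2 groups alone in the fit there were 0 for CsA 48 h, 1 for Fk 48 h, 651 for Ra 12 h, 0 for Ra 48 h, 336 for high Nnm 24 h and 318 for high Nnm 48 h. An estimated correlation between genes gave 0 for gene lists. Splitting the shared controls gave 0.081 for the correlation of Fk and Ra at 48 h.

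In the Fk and Ra set the replicate numbers were not taken to pair the arrays. Of 45 correlations of same-numbered deviations 19 were above 0.1 (mean 0.1, range -0.18 to 0.76, against -0.05 between other numbers). All 3 were above 0.1 within Ra 12 h vs control (0.14, 0.35 and 0.29) and Fk vs Ra 12 h (0.19, 0.34 and 0.25). Fk at 48 h and its controls reached 0.76 and 0.58 for numbers 1 and 3, with -0.02 for number 2. Other splits of these 6 arrays gave at most 1 call where they part the numbers and up to 228 otherwise. A partial pairing in this set thus stays possible. With the replicate number as a block in every set the counts were 1 for CsA 12 h, 498 for CsA 48 h, 1 for Fk 12 h, 8 for Fk 48 h, 77 for Ra 12 h, 3241 for Ra 48 h, 2049 for low Nnm 24 h and 1478 for low Nnm 48 h. Across other comparisons the block gave 3107 for high Nnm 48 h, 5 for Nnm dose 48 h, 5 for Fk vs Ra 12 h, 3071 for Fk vs Ra 48 h, 1339 for Ra by time, 20 for CsA vs Fk at 48 h, 2 for CsA vs Ra at 12 h and 3011 for CsA vs Ra at 48 h. Of list calls in the paired sets the block ended those of fatty acid oxidation for low Nnm 48 h (0.0529) and of interferon-stimulated genes for high Nnm 24 h (0.0507), and of genes it added CDKN1A and ABCB1 for CsA 48 h and CLU, GDF15 and HAVCR1 for Nnm, and it changed no other call reported for those sets. In the Fk and Ra set it ended the list calls of cholesterol (0.0505) and kidney injury (0.0534) at 48 h and called CDKN1A (0.0239). The block with the compared set alone in the fit gave 13 for CsA 48 h, 1 for Fk 48 h, 1359 for Ra 48 h, 2977 for low Nnm 24 h, 2348 for low Nnm 48 h and 4891 for high Nnm 24 h. That fit also gave 4056 for high Nnm 48 h, 0 for Nnm dose 24 h, 0 for Nnm dose 48 h, 0 for Fk vs Ra 12 h, 1165 for Fk vs Ra 48 h and 95 for Ra by time. With the block and without CsA arrays of number 1 there were 274 for CsA 48 h and 5 for CsA by time, without those of number 2 2 for CsA 12 h and 2 for CsA by time, and without those of number 3 1 for CsA 12 h and 74 for CsA 48 h. The block without Nnm arrays of number 1 gave 364 for low Nnm 24 h, 187 for low Nnm 48 h, 989 for high Nnm 24 h, 799 for high Nnm 48 h, 0 for Nnm dose 24 h, 0 for Nnm dose 48 h and 0 for high Nnm by time. Without those of number 2 it gave 2312 for low Nnm 24 h, 1777 for low Nnm 48 h, 4326 for high Nnm 24 h, 3537 for high Nnm 48 h, 814 for Nnm dose 24 h, 430 for Nnm dose 48 h, 10 for low Nnm by time and 393 for high Nnm by time. Without those of number 3 it gave 227 for low Nnm 24 h, 249 for low Nnm 48 h, 1001 for high Nnm 24 h, 892 for high Nnm 48 h, 0 for Nnm dose 24 h, 0 for Nnm dose 48 h and 0 for high Nnm by time.

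Without Ra 48 h replicate 2 and Fk 12 h replicate 3 there were 198 for CsA 48 h, 1 for Fk 12 h, 5 for Fk 48 h, 66 for Ra 12 h, 1067 for Ra 48 h, 1576 for low Nnm 24 h and 1084 for low Nnm 48 h. Between effects there were 2 for Nnm dose 24 h, 1 for Nnm dose 48 h, 0 for Fk vs Ra 12 h, 768 for Fk vs Ra 48 h, 163 for Ra by time, 2 for high Nnm by time and 8 for CsA vs Fk at 48 h. Adding the block to that gave 2 for CsA 12 h, 1129 for CsA 48 h, 3 for Fk 12 h, 34 for Fk 48 h, 538 for Ra 12 h, 3168 for low Nnm 24 h, 2578 for low Nnm 48 h, 4960 for high Nnm 24 h and 4215 for high Nnm 48 h. For differences it gave 20 for Nnm dose 24 h, 5 for Nnm dose 48 h, 10 for Fk vs Ra 12 h, 1143 for Ra by time, 9 for high Nnm by time, 166 for CsA vs Fk at 48 h, 3 for CsA vs Ra at 12 h and 3095 for CsA vs Ra at 48 h. With the block and without Ra 48 h replicate 2 alone the counts were 1 for CsA 12 h, 840 for CsA 48 h, 20 for Fk 12 h, 12 for Fk 48 h, 349 for Ra 12 h, 2714 for low Nnm 24 h, 2142 for low Nnm 48 h and 4498 for high Nnm 24 h. The others there were 3753 for high Nnm 48 h, 6 for Nnm dose 24 h, 6 for Nnm dose 48 h, 63 for Fk vs Ra 12 h, 806 for Ra by time, 40 for CsA vs Fk at 48 h and 3 for CsA vs Ra at 12 h. Leaving out these 2 arrays and the Nnm arrays of number 2, with the block, gave 1 for CsA 12 h, 1427 for CsA 48 h, 4 for Fk 12 h, 82 for Fk 48 h, 840 for Ra 12 h, 3738 for low Nnm 24 h, 3159 for low Nnm 48 h, 5616 for high Nnm 24 h, 4907 for high Nnm 48 h and 2177 for Nnm dose 24 h. Differences in that fit numbered 942 for Nnm dose 48 h, 29 for Fk vs Ra 12 h, 1 for CsA by time, 1591 for Ra by time, 76 for low Nnm by time, 1381 for high Nnm by time, 274 for CsA vs Fk at 48 h, 12 for CsA vs Ra at 12 h and 3524 for CsA vs Ra at 48 h.

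Leaving out 1 array at a time, where a group of 2 was taken to vary as the others did, gave ranges of 0 to 1 for CsA 12 h, 2 to 391 for CsA 48 h, 0 to 5 for Fk 12 h, 0 to 5 for Fk 48 h, 1 to 11 for Ra 12 h, 817 to 3084 for Ra 48 h and 194 to 1303 for low Nnm 24 h. The ranges were 131 to 955 for low Nnm 48 h, 853 to 3856 for high Nnm 24 h, 578 to 2928 for high Nnm 48 h, 0 to 1049 for Nnm dose 24 h, 0 to 228 for Nnm dose 48 h, 0 to 32 for Fk vs Ra 12 h and 555 to 3062 for Fk vs Ra 48 h. They were 0 to 10 for CsA by time, 0 to 1 for Fk by time, 83 to 1479 for Ra by time, 0 to 216 for high Nnm by time, 0 to 34 for CsA vs Fk at 48 h, 898 to 2692 for CsA vs Ra at 48 h and 0.044 to 0.15 for the correlation of CsA and Fk at 48 h. For the rest, with replicate numbers left out for the correlations, they were -0.455 to -0.304 for the correlation of CsA and Ra at 48 h, 0.294 to 0.371 for the correlation of Fk and Ra at 48 h, -0.001 to 0.045 for the correlation of CsA and Nnm at 48 h, 0.25 to 0.283 for the correlation of Fk and Nnm at 48 h and 0.051 to 0.123 for the correlation of Ra and Nnm at 48 h. The CsA and Nnm correlation thus turned to -0.001 without replicate 1. Of the list calls, that named immediate early genes, Fk 12 h vs control lay at 5.32e-05 without replicate 1. It turned upward without replicate 3 (0.776) and without the 2 arrays (0.72), and that of ion and water homeostasis for Fk 12 h turned upward without the 2 arrays (0.998). Of 69 called lists 42 kept their call under each alternative other than the estimated correlation, and 23 lost it with a replicate number left out.

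Under the remaining alternatives the counts stayed within 1.5 times. For the genes named, 8152 comparisons with an alternative kept direction and call, 1830 lost the call, 74 gained it and 0 changed direction, and for the lists 751 kept both, 143 lost the call and 3 changed direction. For the change of the controls with time the counts of 1554, 2252 and 0 genes (CsA, Fk and Ra, and Nnm set) became 2734, 3401 and 80 with the block and ran from 638, 1108 and 0 upward with 1 array left out. Signal over background set the genes that could be seen: 11356 genes had a probe set above log2 4 in at least 3 arrays.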

Other observations

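The comparisons of control cells over time, and the tests of RNA quality and array scale on them, were chosen only after the values were seen, while the predictions for the correlations with the compounds' effects were written before those correlations were computed, though after the list results were known.

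Control cells themselves changed between 12 h and 48 h. Targets of ATF4 and CHOP rose in the vehicle controls, 23 of 30 in the CsA set and 24 of 30 in the Fk and Ra set (camera adjusted p = 4.67e-21 and 7.43e-17; adjusted p = 0.217 and 0.238 with an estimated correlation). DDIT3 went from 7.77 to 13.16 and from 8.46 to 13.43, INHBE rose by 5.47 and 7.2, and the cystine transporter SLC7A11 by 5.08 and 3.97. Chaperone and degradation genes of the endoplasmic reticulum rose too, 17 and 12 of 24 (adjusted p = 3.04e-15 and 1.38e-08; adjusted p = 0.269 and 0.689 with an estimated correlation). Genes of DNA replication fell, 21 and 24 of 29 (9.33e-16 and 5.13e-18; adjusted p = 0.269 and 0.238 with an estimated correlation), as did those of G2 and mitosis, 22 and 25 of 28 (3.21e-15 and 6.39e-15; adjusted p = 0.397 and 0.543 with an estimated correlation). TXNIP, which glucose induces, fell in these sets (-4.57 and -5.18), and in the Nnm set controls it stood at 9.32 at 24 h and 5.89 at 48 h (-3.42, adjusted p = 0.185).

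In all, 1554 genes changed in the CsA set controls (695 higher, 859 lower) and 2252 in the Fk and Ra set controls (1149 higher, 1103 lower). Without 12 h replicate 3 or 48 h replicate 2 the former was 703 or 638, and without 12 h replicate 3, 48 h replicate 1 or 48 h replicate 2 the latter was 1466, 1108 or 1427. Between 24 h and 48 h limma called 0 genes in the Nnm set controls (664 at an unadjusted p under 0.05, 80 called with the replicate number as a block), where DDIT3 stood at 7.97 and 9.52 (adjusted p = 0.831). As lists, genes of G2 and mitosis and of DNA replication shifted downward there too (camera adjusted p = 4.69e-12 and 5.91e-08, and 0.75 for each with an estimated correlation). RNA quality is argued against as the source in the CsA set by a shift of 0.04 in the mean ACTB 3′ to 5′ difference, within its SD. In the Fk and Ra set controls RNA quality stays open, as that difference rose by 0.19, from 1.07 (SD 0.08) to 1.25 (SD 0.15). Array scale is argued against in the CsA set by a median change of 1.8 for the ATF4 and CHOP targets with centred arrays. A response of the cells to time in culture may account for the change, but medium, density and other handling were not tested.

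A hypothesis from these values is that CsA pushed the cells further along the change that control cells undergo with time, and that Ra held it back. It was tested against the controls of the other set, which share no array with the effect. The effect of CsA at 48 h correlated at 0.43 (Spearman 0.39) across genes with the time change of the Fk and Ra set controls, and at 0.32 to 0.48 with a replicate number left out. The effect of Ra at 48 h correlated at -0.61 (Spearman -0.52) with the time change of the CsA set controls, and at -0.58 to -0.49 with a replicate number left out. Fk (-0.02) and the high dose of Nnm (0.03) lay near 0. The values are consistent with the hypothesis, but genes are not independent replicates, and a difference between wells in density or medium could give the same axis.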
